A study of Mus musculus with 4 samples.

How the data were processed

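RNA from mouse zygotes was sequenced in 4 samples: MO control, MO injected, S31A control and S31A injected. Per the labels' protocols, total RNA was used, cDNA was amplified by PCR and libraries were made with an NEBNext Ultra II DNA kit. Per the submitters' processing notes, FastQC, Bowtie2, featureCounts and DESeq2 were used with the mm10 genome build; their versions, the annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here. Bowtie2 does not split reads across introns, so reads over exon junctions of a spliced gene can be lost or placed on an intronless copy, and which of these happened was not given. Without a stated strand setting, overlapping and antisense genes are uncertain.

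The deposited values were raw counts per gene, whole numbers with no normalization, for 55291 features. The gene lengths in bases were also as deposited, per the file headers. Of the feature symbols, 96.4% were found in GENCODE M21, and 95.7% had the same chromosome, start and end there, so coordinates are those of mm10. Each sample had 2 count columns, and the names of these columns carry numbers 1 and 2. No source says whether they are separate pools of embryos or repeat preparations. They are called libraries here. A chi-square test of counts per gene gave 51.5 to 130.4 per degree of freedom between the libraries of a sample, so they were not copies of a single library, and they were not counted as replicates. No per-sample column was left out. Depth was 5661621 to 13233371 counts per library, with 11372 to 15156 genes detected and 3.47% to 10.36% of counts on mitochondrially encoded genes. PCR copies cannot be told from separate molecules without molecular identifiers, so intervals and floors cover counting error only.

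The following choices were made before the data were examined. Counts were summed per sample and scaled with edgeR's TMM factors (edgeR 4.0.16, R 4.3.3). The log2 ratio of CPM, with a prior count of 2, was the main value, over genes at 10 CPM or more in at least 1 of the 2 samples compared, and genes at least 2-fold apart were counted. With 1 sample per group no test between groups was possible and none was made from the sums. Intervals of ratios are exact 95% Clopper-Pearson intervals of the share of counts, and a ratio against 0 counts is given as a lower bound with a floor of 3 counts over the summed sample. In gene lists, placing such members at their bound changed a median only for cumulus and granulosa cell markers, from -2.97 to -2.69 with S31A injection and from 3.70 to 3.23 between controls.

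There were 22 gene lists. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, where at least 3 members were measured. Named genes were the 12 highest and the 12 lowest per comparison by the interval bound nearest to no change, with a ratio of at least 2-fold, at least 50 counts and a symbol that is not a predicted, clone, Mir or Snor name. To these were added the H3.3 genes and up to 4 members per list with the largest absolute log2 ratio. Other than the H3.3 genes, a gene was named by this rule only where all injected libraries lay on 1 side of all control libraries; H3f3a overlapped in the S31A experiment. Zscan4d, Klf17, Gm20767, Gm21761, Tcstv1, Tcstv3, Cyp19a1 and the features Gm6485 and Gm37486, and the genes named in the comparison of controls, fall outside this rule or part of it and were chosen after their values were seen.

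edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment) and DESeq2 1.42.0 were run over the libraries. Their p-values measure only the spread between libraries of 1 sample, which may be technical. A test of the S31A ratio minus the MO ratio over all 8 libraries used the same edgeR model with an interaction term. Copies of H3f3a and H3f3b were found by aligning the 411-base coding sequences to GENCODE M21 transcripts with BLAST+ 2.17.0, at 85% identity and 80% coverage or more. This gave 47 copies closer to H3f3a and 2 closer to H3f3b.

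The steps were tested on simulated counts drawn for the measured genes, with gene-wise dispersions around the fitted trend and 200 changed genes, 50 at each fold size. In the MO simulation over 8110 genes, edgeR recovered 1, 0, 8 and 32 of the 50 genes changed by 2, 4, 16 and 64-fold, with 2 false calls, and DESeq2 recovered 6, 14, 44 and 49 with 165 false calls. In the S31A simulation over 8191 genes, edgeR recovered 0, 0, 7 and 17 with 0 false calls, and DESeq2 recovered 1, 10, 38 and 42 with 232 false calls. Of the unchanged simulated genes, 28.7% and 38.4% were at least 2-fold apart in the MO and S31A simulations. A planted list of 40 genes raised 2-fold reached percentile 100 in both, and 2 of 40 unchanged lists fell outside the central 95% in each. In the data 11.3% of measured genes were at least 2-fold higher and 12.5% lower with MO, and 14.1% and 16.1% with S31A. Higher and lower genes added were fewer than the unchanged simulated share in each experiment. The simulations thus spread genes more widely than the data. Their recovered genes and false calls may therefore not describe these libraries.

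Alternatives tried were other scalings, prior counts, filters and fold thresholds, thinning to the shallowest library, leaving out mitochondrial genes, removing trends on gene length or mean expression, other random lists, tests over the libraries and leaving out each library. Figures were drawn with matplotlib 3.10.9.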

Results

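RNA-seq was performed on mouse zygotes, the fertilised egg before its first division. At this stage most RNA was stored in the egg by the mother, and transcription from the embryo's own genome is only beginning. The series asks how histone H3.3 made from maternal RNA acts on the parental genomes during this minor wave of genome activation. H3.3 is the histone H3 variant that is placed on chromatin outside DNA replication, and in the mouse it is encoded by H3f3a and H3f3b, whose proteins are identical. There were 4 samples and 1 in each group. Zygotes labelled as injected with an H3.3 MO were set against their own control, and zygotes labelled as injected with H3.3 S31A against a separate control. The labels do not spell out MO, which in embryo injection work usually stands for morpholino, a synthetic antisense oligonucleotide. A morpholino blocks translation or splicing and need not lower the mRNA, so neither direction of the H3.3 counts was assumed beforehand. S31A is the usual notation for a serine replaced by alanine. What the control zygotes received was not given in the sources used here.

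The deposited count table held 2 columns for each sample, called libraries 1 and 2 below. Their totals ran from 5661621 to 13233371 counts, and the summed totals were 14806944 for the MO control, 22414123 for the MO injected, 21700991 for the S31A control and 22094332 for the S31A injected sample. Because each group was 1 sample, the differences have no replicate check. Values are given per library, and intervals cover counting error only.

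The H3.3 genes came first because the injections address them. In the MO control libraries H3f3b, on chromosome 11 from 116021912 to 116027962 in mm10, stood at 2199 and 1550 CPM, counts scaled to a common library total. In the MO injected libraries it stood at 2.30 and 10.5 CPM. Summed over libraries, H3f3b was 330-fold lower after MO injection (log2 ratio -8.34, 95% interval -8.63 to -8.11). H3f3a, on chromosome 1 from 180800832 to 180813943, was 18.7-fold lower (log2 ratio -4.22, interval -4.35 to -4.10), from 462 and 586 CPM to 8.04 and 52.4 CPM. Both injected libraries lay below both control libraries for both genes. Without MO injected library 1 the log2 ratios of H3f3b and H3f3a were -7.545 and -3.31, and without MO injected library 2 they were -9.685 and -6.00.

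In the S31A experiment, H3f3b was 1.58-fold higher in the injected sample (log2 ratio 0.66, interval 0.64 to 0.67), at 2438 and 2749 CPM against 1453 and 1819 CPM. H3f3a stood at 484.5 and 648 CPM against 657 and 563 CPM, so its libraries overlapped. A far larger difference appeared at Gm6485 and Gm37486, a pair of intronless copies of the H3f3b coding sequence. Gm6485 lies on chromosome 3 from 104752727 to 104753165 and Gm37486 on chromosome 1 from 178299396 to 178299800, and they are annotated as a transcribed processed pseudogene and a processed pseudogene. They aligned to the H3f3b coding sequence at 92.3% and 96.8% identity. Gm6485 rose 74.2-fold, from 171 and 157 CPM to 8172 and 17050 CPM, with a log2 ratio of 5.612 to 6.655 over the alternatives. Gm37486 rose 75.4-fold, from 127 and 98.0 CPM to 5798 and 11690 CPM, with a log2 ratio of 5.665 to 6.658 over the alternatives. These were the only features of the 8191 tested that passed edgeR's quasi-likelihood test over the libraries (Benjamini-Hochberg adjusted p = 0.0491 for each at a filter of 10 CPM, 0.00812 at 1 CPM and 5.99e-06 at 50 CPM, higher in both injected libraries). In the MO experiment the same features were lower in the injected sample, with 25 and 4 counts left. The log2 ratio of Gm6485 was -6.94 (interval -7.69 to -6.50), and -8.57 without MO injected library 2 and -6.045 without MO injected library 1. That of Gm37486 was -8.83 (interval -11.34 to -8.10), and -9.46 and -8.23 without these libraries. H3f3b and these copies share most of their coding sequence, and how reads matching several of them were divided was not given in the sources used here.

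**Figure D1:**
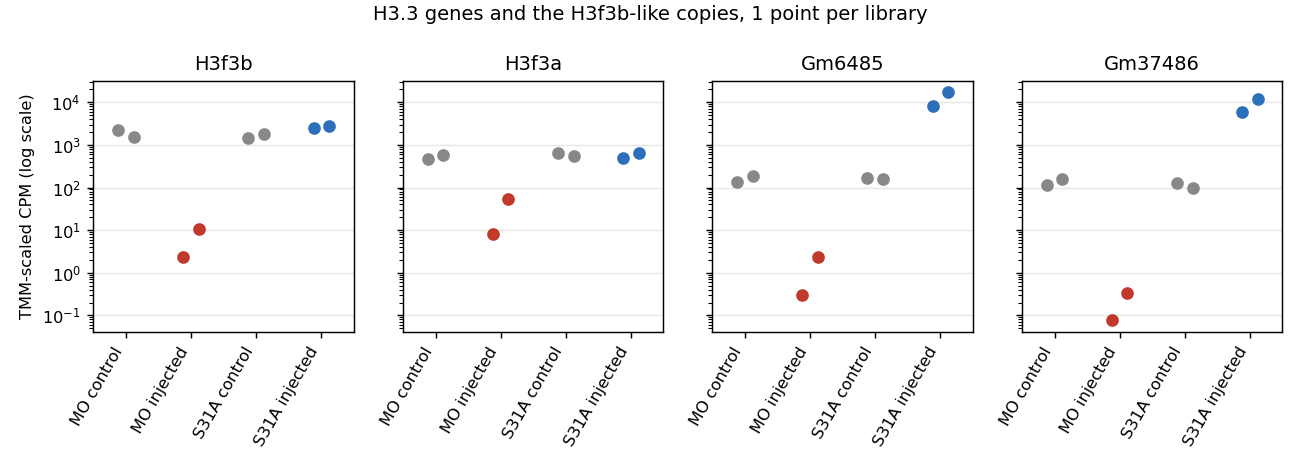
TMM-scaled CPM on a log axis for H3f3b, H3f3a and the H3f3b-like copies Gm6485 and Gm37486, with 1 point per library and 2 libraries per sample. The MO injected libraries lie below all others in each panel (2.30 and 10.5 CPM for H3f3b), and the S31A injected libraries reach 8172 and 17050 CPM at Gm6485.

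The comparison of MO injected with MO control zygotes asks what else differed when counts of the H3.3 genes were low. Of 8110 measured genes, 913 were at least 2-fold higher and 1017 at least 2-fold lower in the injected sample. These were 11.3% and 12.5% of measured genes. In the MO simulation 28.7% of unchanged genes were at least 2-fold apart, but that simulation spread genes more widely than the data. Its share therefore cannot tell whether the injection changed genes. Of 8300 genes at 10 CPM or more in a library of the MO control, 61 had 0 counts in the other. In the MO injected sample this held for 299 of 8273. The bounds on ratios below cover counting error only and do not separate injection from such gaps between libraries. Genes with none or nearly no counts in the control and clear counts in both injected libraries included Olfml2a (at least 72.1-fold higher, 15.8 and 10.6 CPM), Far2, a reductase that makes fatty alcohols (at least 70.2-fold, 10.4 and 17.4 CPM), N4bp2l1 (log2 ratio 5.72, interval 4.75 to 8.60, 8.04 and 25 CPM) and Trim38 (66.4-fold, 10.5 and 25.7 CPM). On the lower side, Gab1, an imprinted adaptor of growth factor receptors, went from 22.6 and 14 CPM to 0 counts in both injected libraries (at least 137-fold lower). Cnga4, a subunit of the olfactory ion channel, was at least 98.5-fold lower, and the zinc finger gene Zfp418 at least 88.3-fold lower. Pcnx4 was 105-fold lower, from 37.8 and 28.9 CPM to 0 and 0.764 CPM. With 3 or fewer counts left in the injected sample, Simc1 had a log2 ratio of -5.97 (interval -9.04 to -5.19), Zfp94 of -5.88 (-8.95 to -5.10) and Grhl2 of -5.78 (-9.89 to -4.96). Fam120c stood at -5.34.

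Some of the named genes rested mainly on 1 library. Muc3, a mucin, was at 23.8 CPM in 1 MO injected library and 0.109 CPM in the other. Nagpa, Col9a3 and Adcyap1r1 showed the same split, at 19.3 and 1.31, 17.2 and 1.97, and 30.1 and 1.64 CPM. Wdr73 stood at 0.435 and 30.7 CPM in the MO control libraries, and Chpf at 21.2 and 0.164 CPM. Ap5s1 and Map6d1, at 0 counts in the control, were at least 69.7-fold and 58.3-fold higher, and Armc7, at 0 counts after injection, was at least 74.7-fold lower. Cacna1b had a log2 ratio of 5.41 (interval 4.44 to 8.29) and Unc5a of 4.52.

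With MO injection, none of the 16 lists with at least 3 measured members had a median outside the central 95% of random lists matched on expression. The 2-cell-stage genes, which mark the wave of embryonic transcription after the first division, came nearest with a median log2 ratio of -0.55 over 7 measured members (percentile 2.95). Their lower members were Duxf3, a multicopy homeobox gene that switches on this programme (-2.53), and Arg2 (-1.57); Zfp750 stood at -0.61 and Sp110 at -0.55. Among cell cycle genes, 5 of 37 measured members were at least 2-fold lower and 1 was higher (median -0.14, percentile 5.80). Of all measured genes 12.5% were lower and 11.3% higher, so the share of lower members was close to that of all genes. Bub1, a kinase of the spindle checkpoint, had a log2 ratio of -1.95, the cyclin-dependent kinase Cdk2 -1.85, the mitotic inhibitor kinase Wee1 -1.77 and the phosphatase Cdc25b -1.22. Wee1 was uneven between the MO injected libraries, at 1.84 and 11.2 CPM against 18.15 and 23.8 CPM in the controls. The factors that deposit or chaperone H3.3 had a median of 0.11 over 11 members (percentile 51.84). Of these, only the remodeller Chd1 was at least 2-fold lower (-1.75), while Nasp stood at -0.96, Ubn1 at 0.63 and Asf1b at 0.47.

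Oocyte and maternal-effect genes had a median of 0.08 over 46 members (percentile 37.78), with 8 at least 2-fold higher and 6 lower. H1f8, the oocyte linker histone, was 4.39-fold higher, at 5338 and 1214 CPM against 1180 and 374 CPM, and Astl, the protease that hardens the egg coat, was 4.42-fold higher, at 143 and 40.7 CPM against 20 and 29.3 CPM. Both rested mainly on MO injected library 1, without which the log2 ratios were 0.47 for H1f8 and 0.75 for Astl. Oosp2 and Ccnb3 had log2 ratios of -1.54 each, although Ccnb3 was at 0 in 1 injected library and 56.9 CPM in the other. Among maternal mRNA decay factors (median 0.13, percentile 58.93), Cnot1, the scaffold of the deadenylase complex, was lower (-1.92) and the decapping factor Dcp1a higher (1.38), and Dcp2 stood at -0.92. Parental genome reprogramming enzymes had a median of 0.08 over 33 members (percentile 48.52). Dnmt1, the maintenance DNA methyltransferase, stood at -0.89, Kmt2b at 0.54, Crebbp at -0.49 and Kmt2c at 0.35. Major genome activation genes had a median of -0.09 over 21 members (percentile 22.22), and their lower members were the chaperonin subunit Cct5 (-1.59) and the RNA polymerase II subunit Polr2b (-1.21).

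The remaining lists also lay within the range of random lists. Cell stress genes had a median of -0.01 over 12 members (percentile 45.84), with the small heat shock protein Hspb1 at 2.54 and the immediate early gene Egr1 at -1.72. Egr1 was uneven between the MO injected libraries, at 1.99 and 17.9 CPM against 20.65 and 42.7 CPM in the controls. p53 and DNA damage genes stood at 0.08 (percentile 56.48), including Btg2 at -1.33 and Trp53 at 0.83. Pluripotency and trophectoderm genes stood at 0.385 (percentile 91.78), including Dppa2 at -1.60 and Gata3 at 0.77. Medians were 0.37 for Obox genes (4 measured members, percentile 82.76) and 0.41 for ribosomal protein genes (7 members, 84.02). They were -0.06 for paternally expressed imprinted genes (5 members, 46.13) and 0.54 for maternally expressed imprinted genes (6 members, 89.85). Interferon-stimulated genes stood at -0.75 (3 members, 10.75) and mitochondrially encoded genes at -0.14 (10 members, 11.20). Of the replication-coupled H3 genes, 0 of 12 were measured. Single libraries changed which lists lay outside the central 95%: without MO control library 1 the Obox median was 1.12 (percentile 99.54), without MO control library 2 the cell cycle median was -0.29 (0.47), and without MO injected library 2 the mitochondrial median was -0.52 (2.23). Without MO injected library 1 the medians were -0.68 for 2-cell-stage genes (1.97), -0.20 for oocyte and maternal-effect genes (0.26) and -2.145 for interferon-stimulated genes (1.78).

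All libraries lay on 1 side for 591 of the higher and 842 of the lower genes. At any size this held for 40.5% of measured genes, where chance gives 33.3%. Between the S31A control and the MO control it held for 46.4%, so a share above chance was not particular to injection. No gene passed edgeR's quasi-likelihood test over the libraries of the MO experiment. The smallest Benjamini-Hochberg adjusted p from edgeR was 0.0644, 429 genes had an unadjusted p under 0.05, and DESeq2 called 25 genes higher and 29 lower. For H3f3b and H3f3a the adjusted p was 0.146 and 0.825 from edgeR, and 9.83e-40 and 7.495e-06 from DESeq2. At a filter of 50 CPM edgeR passed H3f3b (adjusted p = 0.01255), Gm37486 and Gm23935 (0.00848 each). The counts of genes moved with single libraries: without MO control library 1 they were 1405 higher and 1531 lower, and without MO injected library 2 there were 1885 lower. With scaling by total counts alone there were 714 higher and 1261 lower. Pairs of libraries from the same MO sample had 24.8% and 39.8% of genes at least 2-fold apart, within the 24.1% to 47.0% found for injected against control. MO injected library 1 stood apart from the other MO libraries, with 38.0% and 47.0% of genes 2-fold apart from the controls and 39.8% from its own partner. MO injected library 2 differed from MO control library 1 at 24.1% of genes, about as the controls differed from each other. Without MO injected library 1 there were 653 genes higher and 1141 lower.

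**Figure D2:**
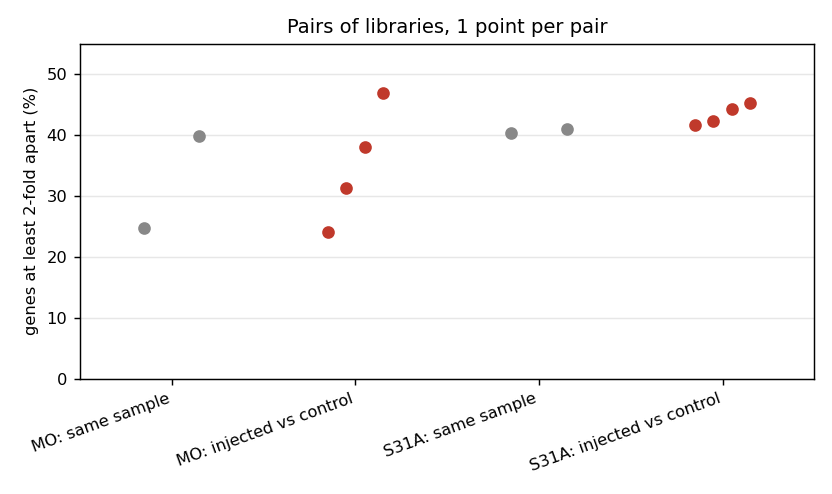
Share of genes at least 2-fold apart, in percent, for each pair of libraries, with pairs from the same sample in grey and injected against control pairs in red. In the MO experiment the same-sample pairs (24.8% and 39.8%) fall inside the range of the injected against control pairs (24.1% to 47.0%), and in the S31A experiment they lie at 40.4% and 41.0% against 41.7% to 45.3%.

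The comparison of S31A injected with S31A control zygotes asks what differed when the mutant H3.3 was supplied. Of 8191 measured genes, 1155 were at least 2-fold higher and 1322 at least 2-fold lower in the injected sample. These were 14.1% and 16.1% of measured genes. In the S31A simulation 38.4% of unchanged genes were at least 2-fold apart, but it too spread genes more widely than the data. That share cannot tell whether the injection changed genes. Of 8411 genes at 10 CPM or more in a library of the S31A control, 706 had 0 counts in the other. In the S31A injected sample this held for 676 of 8241. The bounds on ratios here and on the lower side cover counting error only and do not separate injection from such gaps between libraries. Several genes had 0 counts in both control libraries and levels within 2-fold of each other in the injected libraries: Simc1 (35.9 and 34.9 CPM, at least 262-fold higher), the lipid droplet hydrolase Ldah (39.7 and 25.3 CPM, at least 246-fold), Reep3 (26.9 and 29.9 CPM, at least 209-fold), the RNA polymerase III transcription factor subunit Gtf3c6 (24.3 and 26.3 CPM, at least 186-fold), Zik1, Mmd and Trmo. Pax5, a B-cell transcription factor, had 1 count in the controls and 22.3 and 46.6 CPM in the injected libraries (log2 ratio 7.85, interval 7.03 to 14.82). Bdp1, the acetyltransferase gene Kat2a and Nphp4 were also at 0 in the controls, but Bdp1 and Kat2a rested mainly on 1 injected library, at 35.7 and 1.71 CPM and 31.5 and 4.82 CPM.

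On the lower side, Klhl25 went from 27.8 and 60.4 CPM to 0 counts (at least 312-fold lower), and the tight junction gene Cldn12 from 27.8 and 29.6 CPM to 0 (at least 201-fold lower). Ano2, an ion channel gene, was at least 215-fold lower, from 52.8 and 9.85 CPM. Fgd4, Selenop, Dnajb2, Clec10a and the chromatin reader Brpf1 were also at 0 in both injected libraries, at least 146-fold, 130-fold, 132-fold, 136-fold and 147-fold lower. Zfp62 went from 29.8 and 33.3 CPM to 0 and 0.107 CPM, which is 1 count (log2 ratio -7.76, interval -14.68 to -6.89). Nktr, the growth factor receptor gene Kdr and Adgrg5 were lower too, but each was held mainly by 1 control library, such as Kdr at 0.0934 and 39.8 CPM.

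The 2-cell-stage genes were the only list of 16 outside the central 95% of random lists in the S31A experiment, with a median log2 ratio of 0.78 over 8 measured members (percentile 97.73), where chance gives 0.8 lists of 16. Of these, Gm20767 and Gm21761 were at 0 in both controls and at 10.2 and 44.9 CPM and 18.6 and 1.07 CPM in the injected libraries. Zscan4d, a multicopy gene of the 2-cell stage, was at 0 except in S31A injected library 2, at 31.8 CPM. Tcstv1 and Tcstv3 stood at 0.82 and 0.75 with overlapping libraries, while Arg2 (-0.80), Zfp750 (-0.47) and the abundant Klf17 (-0.24) were lower. The list's median was 0.13 without S31A control library 2 and 0.20 without S31A injected library 1, at percentiles 54.91 and 68.18, and 2.23 without S31A control library 1. With a filter of 50 CPM it was -0.24. The list's percentile was 96.67 with libraries thinned to the shallowest, 96.74 without mitochondrial genes, 95.87 at 1 CPM, and 97.44 and 97.39 with prior counts of 0.5 and 5, all inside the central 95%.

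Cell cycle genes had a median of 0.26 over 35 members (percentile 95.70), with the replication licensing inhibitor Gmnn at 1.07, the mitotic activator Cdc20 at 1.13, Mcm5 at -0.94 and the phosphatase Cdc25a at -1.41. Major genome activation genes had a median of -0.275 over 21 members (percentile 5.23), and 8 were at least 2-fold lower against 1 higher. This list's median was -0.40 with thinned libraries (percentile 1.03) and -0.46 without mitochondrial genes (0.53), outside the central 95%. The lower members included the proteasome subunit Psmc4 (-2.98), the translation initiation factor Eif3b (-1.83), Polr2b (-1.74) and the nucleolar protein Nop56 (-1.74). Psmc4 was at 0 in S31A injected library 1 and 3.85 CPM in library 2, against 16.3 and 12.2 CPM in the controls. Cell stress genes had a median of -0.34 over 9 members (percentile 12.33), with 3 at least 2-fold higher and 4 lower. The lower members were Sesn2 at -6.68 (interval -13.60 to -5.80), Egr1 at -3.03, and the heat shock genes Hsph1 at -2.07 and Dnajb1 at -1.24. Sesn2 had nearly all its counts in 1 control library (30.4 and 0.352 CPM).

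Among H3.3 chaperones (median 0.10, percentile 54.43), Asf1a was 2.40-fold higher, at 501 and 615 CPM against 243 and 219 CPM; Asf1b stood at 0.69 and Ubn1 at -0.85. Maternal mRNA decay factors had a median of 0.095 (percentile 52.93). Of 16 measured members 2 were at least 2-fold higher and 1 lower, against 14.1% and 16.1% of all measured genes. Pabpn1l, the partner of the egg's deadenylation machinery, went from 248 and 298 CPM to 48.3 and 103 CPM (-1.91). Zfp36l2 stood at 2.54 with control libraries at 9.998 and 0 CPM, and Xrn1 at 1.81 with control libraries at 9.06 and 3.43 CPM. Ythdf2 stood at 0.74. Parental genome reprogramming enzymes had a median of 0.24 over 29 members (percentile 89.68), with the histone H3 methyltransferase Kmt2b at 1.34, Hdac2 at 1.06, Kdm1b at 0.98 and the imprint protector Trim28 at -1.24. Oocyte and maternal-effect genes had a median of 0.22 over 46 members (percentile 91.79), with the germ cell helicase Ddx4 at 2.06, the sperm chromatin decondensing factor Npm2 at -1.71, the sperm receptor Izumo1r at -1.21 and Astl at -1.16.

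Pluripotency and trophectoderm genes stood at 0.21 (percentile 76.11), with Pou5f1 at -1.47 and Tfcp2l1 at 1.46. The p53 and DNA damage genes stood at 0.14 (percentile 62.97), with 2 of 13 measured members at least 2-fold higher and 3 lower. Among them Sesn2, also a cell stress gene, stood at -6.68, Brca1 at 0.96 and Trp53bp1 at -0.45. Paternally expressed imprinted genes stood at 0.88 over 7 members (percentile 95.08), with Inpp5f at 1.54 and Gab1 at 1.45. Medians were 0.45 for Obox genes (4 measured members, percentile 95.16) and -0.70 for ribosomal protein genes (8 members, 12.47). They were -0.26 for maternally expressed imprinted genes (4 members, 31.58) and 0.27 for interferon-stimulated genes (4 members, 65.60). Mitochondrially encoded genes stood at -0.14 (9 members, 5.38). Without S31A control library 2 the cell stress median was -0.89 (percentile 0.68) and the cell cycle median 0.385 (97.64). Without S31A injected library 1 the median was 1.27 for paternally expressed imprinted genes (98.49) and 0.55 for pluripotency and trophectoderm genes (97.79). Without S31A injected library 2 it was 0.41 for cell cycle genes (99.40) and -0.34 for mitochondrially encoded genes (1.77).

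**Figure D3:**
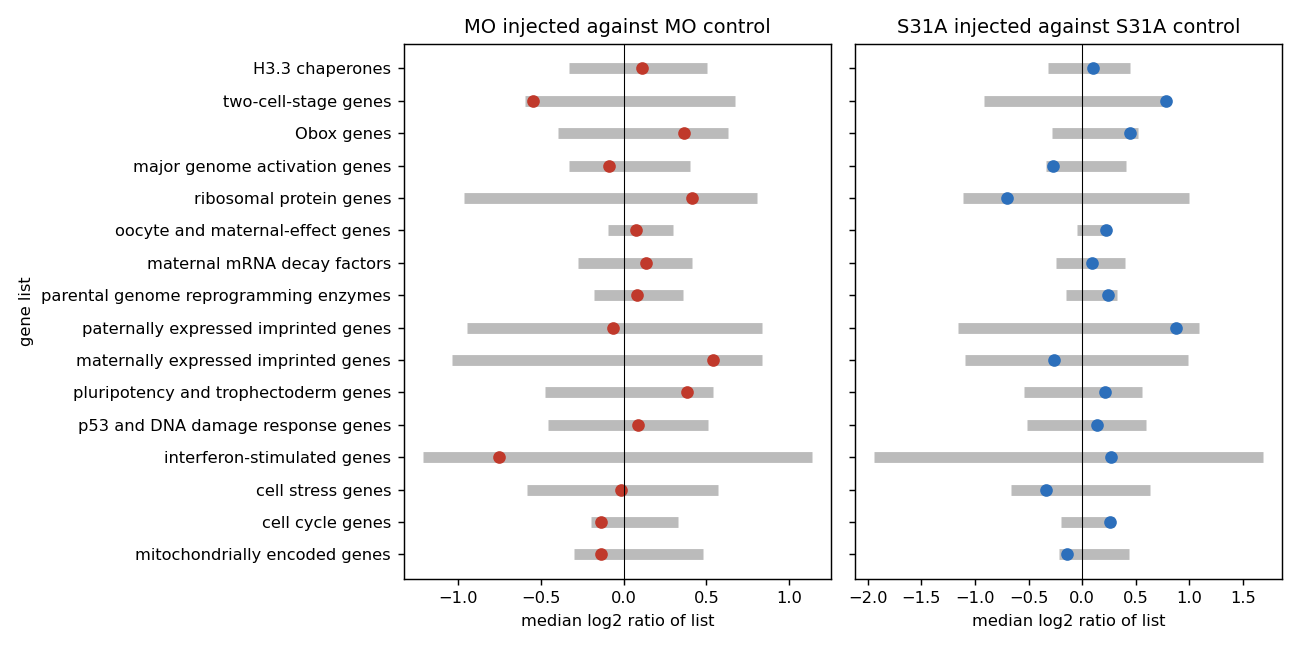
Median log2 ratio of injected to control for each gene list with at least 3 measured members (points), with the central 95% of 10000 random lists matched on mean expression (grey bars). In the MO panel all medians lie inside their bars, and in the S31A panel the 2-cell-stage genes at 0.78 lie just beyond the upper end of 0.76; the axes of the panels differ.

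All libraries lay on 1 side for 753 of the higher and 931 of the lower genes, and at any size for 39.5% of measured genes. That share was 46.4% between the S31A control and the MO control. Apart from Gm6485 and Gm37486, no feature passed edgeR's test over the S31A libraries. There were 490 genes with an unadjusted p under 0.05, and DESeq2 called 290 genes higher and 311 lower. Same-sample pairs of libraries had 40.4% and 41.0% of genes at least 2-fold apart, against 41.7% to 45.3% for injected against control.

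Set against each other across genes, the MO and S31A log2 ratios had a Pearson correlation of 0.05 and a Spearman correlation of 0.09 over 8981 genes, which are not independent replicates. The correlation was -0.004 without MO injected library 1 and 0.005 without S31A injected library 1. Of 7320 genes measured in both experiments, 136 were at least 2-fold higher in both, against 85.7 for independent lists, and 188 were lower in both, against 115.6. In opposite directions, 102 were higher with MO and lower with S31A, and 129 lower with MO and higher with S31A, against 99.6 each. Simc1 and Gab1 were in the last set. The experiments had separate controls, and no test across samples was possible for these overlaps.

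The control samples of the experiments differed as much as injected and control samples did. Between the S31A control and the MO control, 1121 genes were at least 2-fold higher and 1341 lower of 8266 measured. Mitochondrially encoded genes were higher in the S31A control, with a median log2 ratio of 0.95 over 9 members (percentile 100), including mt-Cytb at 28940 against 15020 CPM. Maternal mRNA decay factors were lower (median -0.62, percentile 0.11), with Cnot6 at -1.62, Cnot8 at -1.60 and Xrn1 at -1.57, as were major genome activation genes (median -0.41, percentile 1.51), with Nop56 at -2.66. Klf17 stood at 571 against 2076 CPM. Experiment and any batch cannot be told apart here. No gene passed edgeR's test over these libraries, 818 had an unadjusted p under 0.05, and DESeq2 called 87 higher and 270 lower.

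Markers of other cells were scarce. Summed over each list, blood and immune markers reached at most 32.6 CPM in any library, sperm and spermatid markers 67.9 CPM, cumulus and granulosa cell markers 173 CPM and oviduct markers 222 CPM, while oocyte and maternal-effect genes summed to 39942 CPM or more. None of these 4 marker lists of other cells had over 2 measured members in a comparison, so they were not placed among random lists. Cyp19a1, a granulosa cell aromatase, stood at 74.1 against 43.9 CPM with MO and, with overlapping libraries, at 122 against 63.9 CPM with S31A. Cdh1, on the oviduct list but also made by oocytes, was 1.59-fold higher with S31A, and the sperm list's Odf2 stood at -0.92.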

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

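The tests below were chosen after the results were seen, except those of processed pseudogenes as a class and of the share of genes 2-fold apart by expression level. A test of the difference between the experiments, edgeR's quasi-likelihood interaction term over all 8 libraries with Benjamini-Hochberg adjustment, passed at 3 features; its spread is that between libraries of 1 sample. The S31A log2 ratio exceeded the MO log2 ratio by 15.71 at Gm37486 (adjusted p = 0.000163), by 13.29 at Gm6485 (adjusted p = 0.0029) and by 8.87 at H3f3b (adjusted p = 0.0116). For each, both injected libraries lay below both controls in the MO experiment and above both controls in the S31A experiment. No group had enough samples for a test of outlying samples.

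At Gm6485 and Gm37486 after S31A injection, a general rise at processed pseudogenes is argued against by their median log2 ratio of -0.14 over 684 such features. A higher level of H3f3b itself is argued against too, since the copies exceeded its log2 ratio by at least 4.77 in each pairing of libraries. A candidate explanation is that injected coding RNA of H3f3b type was counted at these intronless copies, which at 439 and 405 bases are close to the length of the coding sequence. The 4 measured copies closer to H3f3a had a median log2 ratio of -0.26, and the ratio of Gm6485 to Gm37486 counts stayed at 1.41 and 1.46 in the injected libraries against 1.35 and 1.60 in the controls. RNA of the H3f3b sequence could also be counted at H3f3b itself, which rose only from 1653 to 2603 CPM. The 2 copies together rose from 278 to 20730 CPM. These values do not favour the candidate, and how reads matching several features were divided was not given. The sequence of the injected RNA was not given in the sources used here either. The candidate and transcription of the copies themselves both stay open.

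For the lower H3f3a and H3f3b counts after MO injection, reads moved to copies are argued against by the copies, of which the highest log2 ratio was -2.72. The choice among 4 scalings does not account for the lower counts, since H3f3a had a log2 ratio of at most -4.21 under each. These scalings shift all genes together and differed little, with MO medians from -0.079 to 0.04. The test could therefore hardly have come out otherwise. A difference between pools of zygotes of the size seen among the 6 other libraries is argued against. There neither gene differed by more than 0.92 log2, while the nearest MO control and injected libraries lay 3.135 apart. This spread leaves out the MO injected pair, which lay further apart, at 2.30 and 10.5 CPM for H3f3b and 8.04 and 52.4 CPM for H3f3a. A spread as wide as that of the MO injected pair is not decided by this test. The injected MO, as the design names it, stays open and untested with 1 sample per group.

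Libraries of the same sample lay far apart. Counting error is argued against by a chi-square of at least 51.5 per degree of freedom. Chance capture of few transcript molecules may contribute: the share of genes 2-fold apart at 100 CPM or more was at most 0.32 times that at 10 to 20 CPM in each of the 4 samples, for example 9.6% against 57.0% in the S31A control. Differences between embryos, if the libraries are separate pools, would need the origin of the libraries to be told and stay open.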

How the results depend on the processing

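The filters at 100 CPM, the requirement that libraries lie on 1 side, the removal of H3.3 genes and copies, the edgeR filters and the leave-one-out values of lists, correlation and controls were chosen after seeing the data. Depth limits genes near the filter, and 1 sample per group limits every count. Counts of genes at least 2-fold apart stayed within 1.5 times under the other scalings, prior counts, thinning, mitochondrial removal and trend corrections. With total counts alone 714 genes were higher and 1261 lower with MO (36.2% higher, against 47.3% with TMM). With S31A injection the share of higher genes was 40.1% to 51.3% over the scalings. The lower counts at stricter and higher counts at looser filters and thresholds follow from the genes admitted. At 1 CPM there were 2376 higher and 3456 lower with MO, 2939 and 3120 with S31A, and 6510 between controls. With no filter these were 3114, 5539, 3577, 3715 and 9229; at 50 CPM 334, 271, 311, 286 and 711; at 100 CPM 176, 120, 131, 108 and 324; at 1.5-fold 1867, 1854, 2042, 2112 and 4252; and at 4-fold 174, 226, 430, 501 and 724. With the counting interval beyond 2-fold, 608 were higher with MO. Requiring both libraries on 1 side left 591 higher with MO and 753 with S31A. At any size 40.5% and 39.5% of genes had libraries on 1 side, and 46.4% between controls, where chance gives 33.3%.

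Over the libraries, edgeR called 0 higher and 0 lower with MO and 2 and 0 with S31A, and DESeq2 25 and 29, and 290 and 311 (54 and 601 in all). With the library number as a replicate block edgeR again called 0 and 0, and 2 and 0; same-numbered libraries did not deviate together (correlation 0.049 and 0.01), so the numbers do not pair them. With 50 CPM edgeR called 3 features with MO (H3f3b, Gm37486 and Gm23935) and 5 with S31A, among them Gm6485, Gm37486, Gm7072 and Gm12346, with fewer genes tested.

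Without each library in turn, genes higher with MO ranged from 653 to 1405 and lower from 966 to 1885, with S31A from 1260 to 1703 and 1538 to 1757, and between controls from 2691 to 3279. The log2 ratio of H3f3b ranged from -9.685 to -7.545 with MO and 0.535 to 0.875 with S31A, and that of H3f3a from -6.00 to -3.31 and -0.36 to 0.05. The correlation ranged from -0.004 to 0.077. Lists outside the central 95%, 1 over both experiments, numbered 1 to 3 without each library, 0 with prior counts of 0.5 or 5, 2 at 1 CPM, 3 at 50 CPM, 2 with no filter, 3 minus the trend on gene length, 2 minus that on mean expression, 2 with unmatched lists and 2 with lists matched on length. Which lists these were changed. With thinning or without mitochondrial genes the number stayed at 1, but it was major genome activation genes with S31A (percentiles 1.03 and 0.53) in place of 2-cell-stage genes (96.67 and 96.74). Cell cycle genes with S31A lay outside at 1 CPM (97.70), at 50 CPM (99.48) and minus the trend on mean expression (99.10), and 2-cell-stage genes with MO at 1 CPM (0.37) and with no filter (0.56). Mitochondrially encoded genes lay outside at 50 CPM with MO (1.90) and S31A (1.21), Obox and oocyte genes with S31A minus the trend on gene length (98.22 and 98.51), and paternally expressed imprinted genes with S31A among unmatched and length-matched lists (98.43 and 98.27). The S31A median of 2-cell-stage genes reversed to -0.241 at 50 CPM, where fewer members are measured. Of 1570 values of named genes under alternatives, 1344 moved by less than the spread between libraries, 226 by more and 0 reversed. Reversal was counted only for genes at least 2-fold apart, and these had been chosen with all libraries on 1 side. The 0 therefore followed largely from the choice of genes and says little about stability. Of 573 list medians, 511 moved by less and 61 by more. The cause was not tested where none is given.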

Other observations

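The tests and genes in this part were chosen after the values were seen. Among abundant genes, at 100 CPM or more in the higher sample, at least 2-fold apart and with all libraries on 1 side, 123 were higher and 110 lower with MO injection. Ccdc117 went from 271 and 199 CPM to 1162 and 956 CPM (4.61-fold), and the circadian repressor Cry1 from 90.3 and 47.8 CPM to 372 and 260 CPM. Prkab1, a subunit of the energy sensor AMPK, went from 34.8 and 24.2 CPM to 344 and 147 CPM. On the lower side, the ubiquitin ligase gene Rad18, which acts in DNA damage tolerance, went from 99 and 119 CPM to 3.29 and 47.4 CPM, the ubiquitin-conjugating enzyme gene Ube2w from 301 and 484 CPM to 60.7 and 123 CPM, and the mitotic helicase gene Ercc6l from 166 and 135 CPM to 24.0 and 37.2 CPM. None of these passed edgeR's test over the libraries (adjusted p of 0.653 for Ccdc117 and 0.825 for the others). For the higher genes DESeq2 gave adjusted p of 5.7e-07 for Ccdc117, 1.9e-05 for Prkab1 and 0.0017 for Cry1. DESeq2 also made 165 false calls in the MO simulation, which spread genes more widely than the data. That number may therefore not describe these libraries. Gm23935, a feature annotated as a miRNA, stood at 743 and 744 CPM against 44.0 and 32.2 CPM with an adjusted p of 0.0644, but its S31A control libraries were at 23.1 and 444 CPM.

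With S31A injection 111 abundant genes were higher and 101 lower. Klhl12 went from 11.5 and 2.55 CPM to 156 and 64.4 CPM, the splicing factor gene Prpf18 from 27.0 and 40.3 CPM to 183 and 132 CPM, and the corepressor gene Rcor1 from 33.4 and 13.7 CPM to 127 and 70.9 CPM. Haspin, the kinase that phosphorylates histone H3 in mitosis, went from 109 and 117 CPM to 18.1 and 40.3 CPM, and the chromatin protein gene Hmgb2 from 86.2 and 154 CPM to 7.42 and 62.4 CPM. The adjusted p from edgeR was 0.802 for each of these except Hmgb2, at 0.805.

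Gm6485 and Gm37486 together took a visible part of the S31A injected libraries, at 0.787% and 0.558% of counts in library 1 and 1.61% and 1.10% in library 2, against at most 0.02% and 0.017% in any control library. Processed pseudogenes as a class, these included, took 5.52% to 7.58% of counts per library. Without the H3.3 copies they took 5.08% and 4.82% in the S31A injected libraries, the lowest of the 8, and 5.45% to 6.77% in the others. Over 50 ribosomal protein genes CPM summed to 187 to 268 per library, while 305 features named as ribosomal protein pseudogenes summed to 619 to 958. Genes at 10 CPM or more in 1 library and 0 counts in its partner numbered 61 of 8300 in the MO control, 299 of 8273 in the MO injected, 706 of 8411 in the S31A control and 676 of 8241 in the S31A injected sample.

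In the difference of the ratios, S31A minus MO, cell stress genes had a median of -0.855 over 13 members (percentile 2.26) and cell cycle genes of 0.34 over 37 members (percentile 98.51). These were 2 of 16 lists outside the central 95% of random lists, where chance gives 0.8.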
